A study of Caenorhabditis elegans with 36 samples.

How the data were processed

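RNA was sequenced from whole Caenorhabditis elegans in 36 libraries, 3 in each of 12 groups. The animals were N2 (the wild type), mbl-1(tm1563) mutants, which carry a deletion allele of the muscleblind splicing factor gene, and transgenic strains that express RNA with 123 CUG repeats (123CUG) or with 0 CUG repeats (0CUG) in body wall muscle. Each construct was present in 2 independent strains, called strain 1 and strain 2 here in the order of the labels. Every genotype was labelled either L4, the last larval stage, or 2-day adult. Per the labels' protocols, animals were synchronised with hypochlorite, grown on HT115 bacteria with an empty RNAi vector and extracted with TRIzol, and libraries were made with an Illumina kit. The labels name 3 libraries per group without saying whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

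The values analysed are the read counts per gene that the authors deposited in 10 tables, each holding 6 libraries of 2 groups. HISAT2, DESeq2 and the genome build WBcel235 are named per the submitters' processing notes. The versions, the counting tool, the annotation release and the strandedness of the library kit are not given in the sources used here. The deposited counts are whole numbers that had not been scaled. Each table lists between 19268 and 21488 genes, unnamed loci included, all with at least 2 reads over its 6 libraries. Of the count values that occur in more than 1 table, 465954 were equal and 0 differed. A gene missing from a table was given a count of 0 in a library only where every table that holds the library lacks it. The deposited tables also hold the authors' log2 fold changes and the authors' p-values for each pair of groups, and only their numbers of genes with an adjusted p-value under 0.05 are cited. The tables were joined into 24931 named genes, and 500 unnamed loci, which took 0.0201% to 0.0643% of the reads of a library, were left out of library sizes and tests. Identifiers and coordinates are those of the deposited tables, with build WBcel235. Symbols were taken from the Ensembl release 115 annotation, in which 24595 identifiers matched and 336 did not. Of the matched genes, 7123 have the same start and end in both, so the gene models behind the counts differ from that release. Overlapping, antisense and near-identical genes can share reads, and values of such genes are uncertain.

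Total counts ranged from 25251114 to 47914774 reads per library. Ribosomal RNA took 0.219% to 9.97% of the reads. The 36 pairs of libraries within groups differed by more than sampling noise: the lowest median chi-square per gene was 1.85, where sampling noise gives 0.455. No pair was therefore treated as 1 library deposited in duplicate.

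The design, the tests, 33 gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined, while settings that leave out doubted libraries or strain-specific genes, or add a covariate, were chosen after. Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after TMM scaling, the filterByExpr filter and robust dispersion estimates, with Benjamini-Hochberg adjustment over all genes tested. A gene is called at an adjusted p under 0.05. mbl-1 was compared with N2 at each stage in a fit of 6 libraries. 123CUG was compared with 0CUG at each stage in a fit of 12 libraries with a coefficient per strain, as the mean of both 123CUG strains minus the mean of both 0CUG strains. Within the same fit the 4 pairs of a 123CUG strain with a 0CUG strain were tested, and genes called in the same direction in all 4 pairs are given separately. The 3 libraries of a strain do not hold the variation between independently made strains, of which there are only 2 per construct. The difference of an effect between stages was tested as an interaction in a fit of the 12 mbl-1 and N2 libraries or of the 24 transgenic libraries, and the stage change of N2 in the former. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM (reads scaled to the library total, in the usual unit of edgeR) computed from the deposited counts on 1 TMM scale over the 36 libraries, as mean ± SD.

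Gene lists cover mitochondrial and lipid metabolism, muscle, neurons, germline and eggshell, cuticle, immunity and detoxification, stress, RNA metabolism and signalling. They were tested with camera of limma 3.58.1 with the correlation between genes estimated from the data, adjusted over the lists of a comparison. Beside it stands the number of members called over all genes and the number called when adjusted over the list alone. Named genes are mbl-1, myo-3 and every cpt gene, the 5 largest rises and falls among called protein-coding genes with a gene name, at least 5 CPM in the higher group and groups whose libraries do not overlap (for 123CUG, called in all 4 pairs), the largest rise and fall of any called gene under the same minimum, and up to 2 called members per direction of each list described. Non-overlap of 3 against 3 libraries arises by chance for 10% of genes. For differences between stages the 3 largest each way are named. Where a group has 0 reads of a gene, the fold is a lower limit computed with 3 reads over the group, and with 1 to 3 reads it is given as a ratio with a 95% counting interval. Such limits and intervals cover counting error only.

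Alternatives were DESeq2 1.42.0, size factors of the RLE method, no expression filter, at least 1 CPM in 3 libraries, protein-coding genes only, at least a 2-fold change, other sets of libraries in the fit, counts summed per strain, each strain left out, each library left out, and the replicate number as a block. For lists they were camera with a preset correlation of 0.01, fry and RLE factors. The whole procedure was tested on simulated data with 200 genes changed per comparison, drawn from tested genes with a mean of at least 5 CPM. No difference between strains of a construct was simulated, so the shares hold for such genes without strain effects. Of the genes changed 2-fold, 100% were called for mbl-1 at L4, 97.0% for 123CUG at L4, 97.0% for 123CUG at the 2-day adult stage and 5.97% for mbl-1 at the 2-day adult stage, where the libraries of a group spread widely. At 4-fold the last share was 72.7%. The position of a library between stages was measured as its median place over 3554 genes that differ at least 4-fold between L4 and 2-day adult in the transgenic strains, on a scale from 0 (their L4 mean) to 1 (their 2-day adult mean).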

Results

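Gene expression was measured by RNA sequencing of whole animals in 12 groups of 3 libraries. The groups were N2 and mbl-1(tm1563) animals, and 2 strains each with 123CUG or 0CUG RNA in body wall muscle, all labelled either L4 or 2-day adult. The questions were which transcripts differ when the splicing factor MBL-1 is disrupted and when its RNA ligand, expanded CUG repeats, is present, with attention to mitochondria. Carnitine palmitoyltransferase, which the study also names, is the enzyme system that takes long-chain fatty acids into mitochondria. Libraries held 25251114 to 47914774 reads.

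The targeted gene, mbl-1 (K02H8.1; chromosome X, 17001728 to 17008361, build WBcel235), was read in every library. In the N2 libraries labelled L4 it stood at 13.1, 13.2 and 13.7 CPM, and in the mbl-1 libraries labelled L4 at 13.7, 9.73 and 15.04 CPM. At the 2-day adult stage it stood at 14.9, 17.3 and 34.6 CPM in N2 and at 14.2, 14.3 and 10.9 CPM in mbl-1. In the transgenic L4 libraries it averaged 36.1 ± 1.73 and 30.9 ± 1.54 CPM (SD, n = 3 per strain) in the 123CUG strains and 31.6 ± 4.63 and 31.5 ± 8.09 in the 0CUG strains. In 2-day adults these averages were 17.3 ± 2.203, 15.8 ± 2.40, 9.11 ± 1.70 and 22.3 ± 1.37 CPM in the same order. Counts over the whole gene do not resolve the part deleted in tm1563, so these levels check no label.

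The N2 and mbl-1 libraries labelled L4 had the transcripts of adults. The yolk protein gene vit-2 (C42D8.2; X, 5101032 to 5106173) averaged 32900 CPM in N2 and 34600 CPM in mbl-1 libraries labelled L4, against 517, 801, 2060 and 1459 CPM in the L4 libraries of 123CUG strains 1 and 2 and 0CUG strains 1 and 2. On the scale from 0 (transgenic L4) to 1 (transgenic 2-day adult), N2 libraries labelled L4 stood at 1.06 ± 0.00560 and mbl-1 libraries labelled L4 at 0.939 ± 0.0294 (SD, n = 3), and the 2-day adult groups at 0.988 ± 0.0609 and 0.934 ± 0.0851. These groups are therefore called the libraries labelled L4, and their comparison is not one of L4 larvae with the transgenic L4 libraries.

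**Figure D1:**
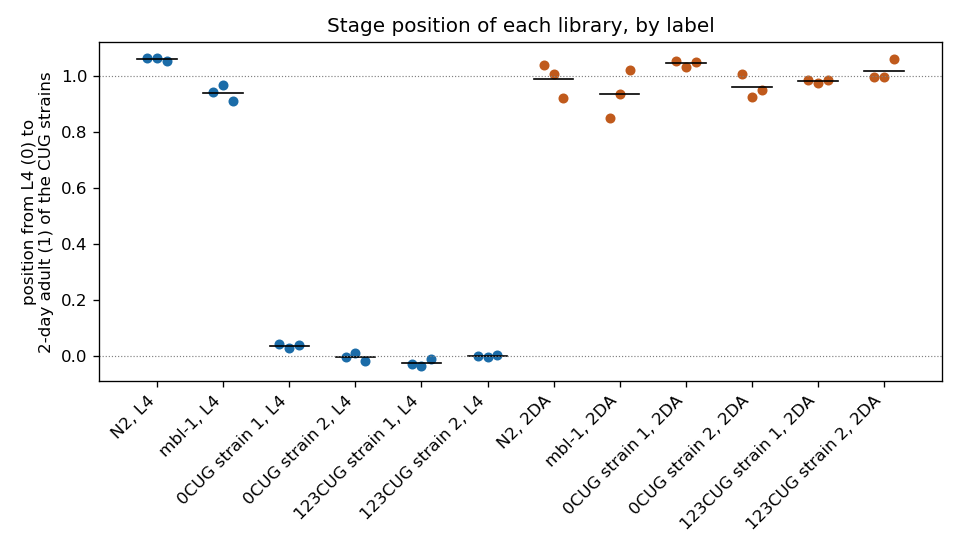
Position of each of the 36 libraries (points, by group) between the transgenic L4 mean (0) and the transgenic 2-day adult mean (1), as the median over 3554 genes; the black line is the group mean. The 6 N2 and mbl-1 libraries labelled L4 lie at 0.908 or higher, beside the 2-day adult libraries.

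In the libraries labelled L4, 41 of 47 body wall muscle genes, 40 of 45 neuronal genes and 93 of 142 intestinal immunity genes rose in mbl-1 against N2, and 17 of 25 oocyte genes and 11 of 13 eggshell genes fell. Camera called none of these lists (adjusted p = 0.619 to 0.641 with an estimated correlation). Libraries labelled N2 also varied along these lists. Relative to the rest of its group, N2 2-day adult replicate 3 had a median log2 difference of 0.628 for muscle, 0.939 for neuronal and -0.900 for oocyte genes. An exchange of its label stays open (below). Whether the shifts in mbl-1 come from the genotype or from a differing share of oocyte transcripts was not tested. cpr-1 (C52E4.1; V, 11975515 to 11976759), a cathepsin B-like protease gene, rose 10.8-fold, from 32.3 ± 4.20 to 355 ± 48.4 CPM (log2 3.43 ± 0.127 SE, n = 3 and 3, edgeR adjusted p = 6.57e-11). ech-9 (F01G10.3; IV, 10233320 to 10235329), of the enoyl-CoA hydratase family, had the largest rise among genes with at least 5 CPM in the higher group and libraries that do not overlap, 18.3-fold to 7.29 ± 0.265 CPM (log2 4.19 ± 0.254, edgeR adjusted p = 1.59e-08). The neprilysin-family gene nep-8 (F18A12.4; II, 3403919 to 3406788) rose 15.3-fold, ifas-1 (F40H7.12; II, 3687791 to 3688691) 13.9-fold and the neuropeptide-like gene nlp-39 (C54C8.9; I, 12461645 to 12462097) 11.1-fold, with edgeR adjusted p of at most 3.06e-08. The largest fall under the same limits was that of skr-12 (C52D10.6; IV, 17167258 to 17168051), a Skp1-related gene, which fell by 2.69 on the log2 scale (SE 0.187, edgeR adjusted p = 6.80e-08). The collagen gene dpy-14 (H27M09.4; I, 6843595 to 6845136) fell by 2.31 (SE 0.323, edgeR adjusted p = 8.35e-05). The ATPase gene catp-3 (C09H5.2; V, 8076085 to 8079849) fell by 2.21, from 52.5 ± 9.27 to 11.5 ± 1.98 CPM. pud-3 (F15E11.15; V, 2324510 to 2325152) fell by 1.83 and the chitinase gene cht-1 (C04F6.3; X, 3397608 to 3400021) by 1.72, and their calls ended without 1 library while the differences stayed of that order. Without mbl-1 replicate 1 pud-3 had a log2 difference of -1.87 (edgeR adjusted p = 0.0662), and without mbl-1 replicate 2 or 3 cht-1 had -1.85 or -1.52 (0.0623 or 0.0673). In all, 3941 genes rose and 2880 fell of 13264 tested, or 51.4%. The falls numbered 1814, 1828 or 1861 without mbl-1 replicate 1, mbl-1 replicate 3 or N2 replicate 2.

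Of 47 body wall muscle genes, 41 rose, 0 fell and 6 were not called, and 42 rose and 1 fell when adjusted over the list alone. Body wall muscle genes had a median log2 of 1.07 (camera adjusted p = 0.619 with an estimated correlation). The muscle myosin gene unc-54 (F11C3.3; I, 14855930 to 14863482) rose from 158 ± 8.56 to 555 ± 101 CPM (log2 1.79 ± 0.119, edgeR adjusted p = 4.51e-08). myo-3 (K12F2.1; V, 12226816 to 12234343), which encodes the other body wall myosin heavy chain, rose from 11.7 ± 0.592 to 26.8 ± 5.50 CPM (log2 1.17 ± 0.138, edgeR adjusted p = 8.32e-06). unc-87 rose by a log2 of 1.70, though F08B6.1 lies antisense to it. Of 45 neuronal genes, 40 rose, 1 fell and 4 were not called, with the same numbers when adjusted over the list alone. Neuronal genes had a median log2 of 1.18 (camera adjusted p = 0.619 with an estimated correlation). Among them the FMRFamide-like peptide gene flp-12 rose from 5.40 ± 0.294 to 19.4 ± 3.46 CPM and flp-11, which has tmem-135 antisense, rose by a log2 of 2.11. The fall of unc-18, by 0.26, was lost without N2 replicate 2 (edgeR adjusted p = 0.0950), N2 replicate 3 (0.136) or mbl-1 replicate 1 (0.158).

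Of 142 intestinal immunity genes, 93 rose, 10 fell and 39 were not called, and 95 rose and 11 fell when adjusted over the list alone. Intestinal immunity genes had a median log2 of 0.74 (camera adjusted p = 0.619 with an estimated correlation). The lysozyme gene lys-4 rose from 85.5 ± 2.08 to 288 ± 41.5 CPM (log2 1.73 ± 0.105, edgeR adjusted p = 1.59e-08) and the C-type lectin gene clec-5 by a log2 of 1.78, while clec-266 fell by 1.55 and clec-91 by 0.81. Of 88 collagen genes, 48 rose, 9 fell and 31 were not called, and 50 rose and 9 fell when adjusted over the list alone. Collagen genes had a median log2 of 0.79 (camera adjusted p = 0.654 with an estimated correlation). Among them col-166 (log2 1.74) and col-34 (log2 2.83) rose, and dpy-17 fell by 1.53, as did dpy-14. Of 21 fatty acid synthesis genes, 14 rose, 1 fell and 6 were not called, with the same numbers when adjusted over the list alone. Fatty acid synthesis genes had a median log2 of 0.50 (camera adjusted p = 0.641 with an estimated correlation). The stearoyl-CoA desaturase gene fat-7 (F10D2.9) rose from 22.7 ± 1.69 to 61.5 ± 4.50 CPM (log2 1.42 ± 0.104, edgeR adjusted p = 9.49e-08) and the desaturase gene fat-3 from 140 ± 10.6 to 293 ± 29.1 CPM, while the fatty acid synthase gene fasn-1 fell by 0.43.

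Of 25 oocyte and early embryo genes, 0 rose, 17 fell and 8 were not called, and 20 fell when adjusted over the list alone. Oocyte and early embryo genes had a median log2 of -0.50 (camera adjusted p = 0.641 with an estimated correlation). mex-3 fell by 0.72, from 429 ± 71.3 to 262.3 ± 50.5 CPM (SE 0.142, edgeR adjusted p = 0.000774), and mex-5 by 0.65. Of 13 eggshell genes, 1 rose, 11 fell and 1 was not called, with the same calls when adjusted over the list alone. Eggshell genes had a median log2 of -0.64 (camera adjusted p = 0.641 with an estimated correlation). cpg-3 fell by 0.85 and egg-3 by 0.62, though each has an antisense gene (R06C7.6 and lurp-1), and perm-2 rose by a log2 of 0.51. Of 52 sperm genes, 38 rose, 3 fell and 11 were not called, and 40 rose and 3 fell when adjusted over the list alone. Sperm genes had a median log2 of 2.23 (camera adjusted p = 0.619 with an estimated correlation). Most were scarce: msp-59, a member of the near-identical major sperm protein family whose reads are uncertain, stood at 1.51 against 0.113 CPM. ssp-37 rose from 11.8 ± 0.181 to 26.4 ± 6.83 CPM, while spe-41 fell by 0.99 and spe-44 by 0.43.

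The 6 measured carnitine palmitoyltransferase genes moved both ways in the libraries labelled L4, with 3 rises and 2 falls over all genes and when adjusted over the list alone (median log2 0.22, camera adjusted p = 0.904 with an estimated correlation). cpt-3 (Y48G9A.10; III, 2082819 to 2088272) rose from 0.432 ± 0.124 to 2.48 ± 1.13 CPM (log2 2.47 ± 0.373, edgeR adjusted p = 8.26e-05). Within N2 2-day adults it stood at 0.349, 0.473 and 3.53 CPM in replicates 1, 2 and 3. cpt-4 (K11D12.4; V, 5023738 to 5027725) rose from 0.262 ± 0.126 to 1.09 ± 0.418 CPM (log2 1.98 ± 0.451, edgeR adjusted p = 0.00230). cpt-5 (F09F3.9; V, 13873172 to 13875878) rose from 15.8 ± 2.75 to 23.6 ± 2.44 CPM (log2 0.56 ± 0.139, edgeR adjusted p = 0.00414). cpt-6 (W01A11.5; V, 6490068 to 6493921) fell by 0.72, from 7.48 ± 0.220 to 4.61 ± 0.2501 CPM (SE 0.152, edgeR adjusted p = 0.00137). The fall of cpt-1 (Y46G5A.17; II, 12787830 to 12796452), by 0.28 from 201 ± 26.9 CPM (edgeR adjusted p = 0.0398), was lost without N2 replicate 2 (0.135), N2 replicate 3 (0.175), mbl-1 replicate 1 (0.116) or mbl-1 replicate 3 (0.122), and its locus overlaps alkb-7. cpt-2 (R07H5.2; IV, 11179643 to 11183000) stood at 117 ± 7.22 against 126 ± 3.26 CPM (log2 -0.12, edgeR adjusted p = 0.263).

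**Figure D2:**
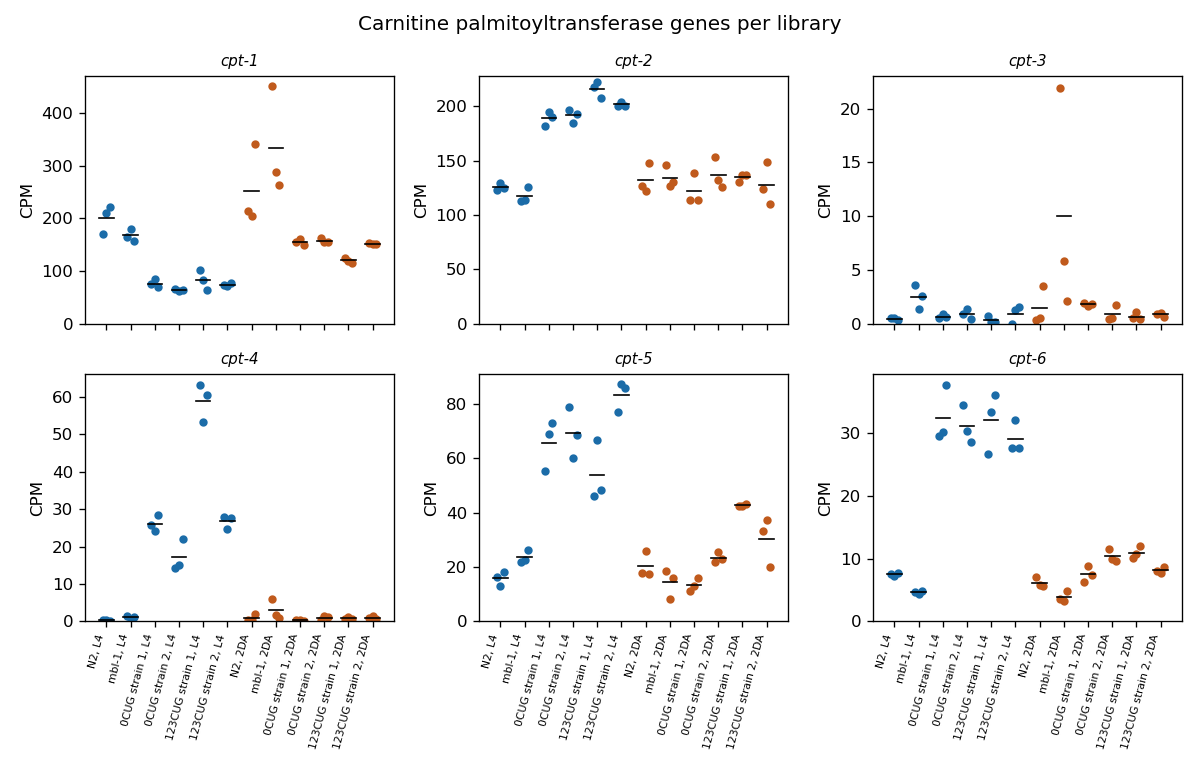
Expression in CPM of the 6 carnitine palmitoyltransferase genes in each library (points), by group, with the mean of each group as a line and axes from 0. cpt-4 averaged 59.0 CPM in L4 libraries of 123CUG strain 1, above 26.7, 26.1 and 17.1 CPM in the other transgenic L4 groups, and cpt-5 averaged 42.6 CPM in 2-day adult libraries of the same strain.

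Peroxisomal genes rose in 16 of 23 cases and fell in 3 (17 and 4 when adjusted over the list alone), with a camera adjusted p of 0.641 with an estimated correlation. Oxidative phosphorylation genes rose in 18 of 38 cases (camera adjusted p = 0.678 with an estimated correlation). Mitochondrial fatty acid oxidation genes rose in 8 of 24 (also 8 when adjusted over the list alone, 0.678). Of 18 mitochondrial dynamics genes, drp-1 and mff-2 fell, but 0 were called when adjusted over the list alone. Over the 33 lists the camera adjusted p lay between 0.619 and 0.976 with an estimated correlation. With a preset correlation of 0.01 camera called 16 lists, and fry called 13.

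DESeq2 called 3622 rises and 3468 falls in the same libraries, and the authors' deposited table has 3531 rises and 3402 falls. With the 12 N2 and mbl-1 libraries in 1 fit, whose 2-day adult libraries spread widely, edgeR called 996 genes. Of the genes called in the fit of 6 libraries, 1697 had an estimated change of at least 2-fold. These were 856 rises and 140 falls, and 1440 and 257, against 3941 and 2880. In the fit of 12 libraries 17 of 40 named genes lost the call, among them unc-54 (edgeR adjusted p = 0.0567), myo-3 (0.0600), cpt-3 (0.124), cpt-4 (0.170) and cpt-5 (0.184), while their log2 differences stayed at 1.79, 1.16, 2.47, 1.99 and 0.55.

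At the 2-day adult stage no gene passed in mbl-1 against N2. edgeR called 0 of 13286 genes (695 at an unadjusted p under 0.05) and DESeq2 57 rises and 75 falls. The authors' deposited table has 46 rises and 62 falls. The genes of interest spread widely within each group. cpt-3 averaged 9.98 ± 10.5 CPM in mbl-1 and 1.45 ± 1.80 CPM in N2 (log2 2.81 ± 1.19, n = 3 and 3). The other log2 differences were 1.82 ± 1.097 for cpt-4, 1.05 ± 0.428 for myo-3, 0.41 ± 0.300 for cpt-1, 0.03 for cpt-2, -0.50 ± 0.344 for cpt-5, -0.65 ± 0.258 for cpt-6 and -0.75 ± 0.359 for mbl-1, with edgeR adjusted p of 0.910 for each and of 0.957 for cpt-2. Leaving out 1 library moved cpt-3 between 1.48 and 4.58, cpt-4 between 0.64 and 3.59 and cpt-1 between 0.11 and 0.66, with each lowest value without mbl-1 replicate 1 and each highest without N2 replicate 3. It moved myo-3 between 0.77 (without N2 replicate 1) and 1.62 (without N2 replicate 3), cpt-5 between -0.77 (without mbl-1 replicate 1) and -0.25 (without mbl-1 replicate 2), and mbl-1 between -0.98 (without N2 replicate 1) and -0.31 (without N2 replicate 3). The median log2 difference was 0.68 for body wall muscle genes (camera adjusted p = 0.898 with an estimated correlation), 0.73 for neuronal genes (0.898), 0.55 for 29 sperm genes (0.396), -0.16 for 86 collagen genes (0.396) and -0.24 for oocyte genes (0.898). Adjusted over the list alone, detoxification genes gave 1 rise and 3 falls and the other lists 0.

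The third library of each 2-day adult group stood apart. Relative to the other two libraries of its group, N2 replicate 3 had a median log2 difference of -0.900 for oocyte genes and 0.628 for muscle genes. In mbl-1 replicate 3 these were 1.16 and -0.448. Without these libraries, an alternative chosen because they stand apart, edgeR called 2957 rises and 1459 falls, among them cpt-3 (adjusted p = 0.00517), cpt-4 (0.00917), myo-3 (0.00282), cpt-6 (0.0410) and cpt-1 (0.0301). With the oocyte list as a covariate, also chosen after, cpt-3 was called (0.0417). mbl-1 replicate 1, which stayed in the fit without the third libraries, stood at -0.971 for oocyte genes relative to the rest of its group. In simulated data 5.97% of genes changed 2-fold and 72.7% of genes changed 4-fold were called in this comparison, so 2-fold differences were mostly not detectable here.

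**Figure D3:**
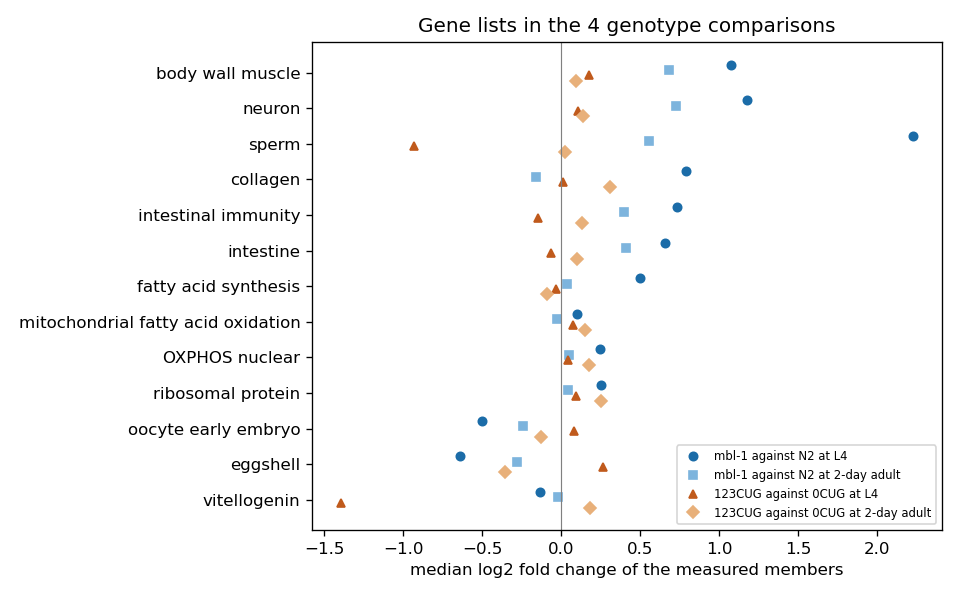
Median log2 fold change of 13 gene lists in the 4 comparisons of genotype (mbl-1 against N2 and 123CUG against 0CUG, each at L4 and 2-day adult). Body wall muscle genes had a median of 1.07 in mbl-1 libraries labelled L4 and vitellogenin genes a median of -1.40 in 123CUG at L4.

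On the stage scale the N2 and mbl-1 groups labelled L4 (1.06 and 0.939) and 2-day adult (0.988 and 0.934) all stood near transgenic adults. Comparisons between these labels therefore test no change from L4 larvae to adults. With the labels as given, the mbl-1 effect differed between stages for 1 of 14027 genes in edgeR (1364 at an unadjusted p under 0.05) and for 173 in DESeq2. The gene, K12B6.11 (V, 6288908 to 6289656), lies outside the rule for naming genes and was chosen after its values were seen. Its interaction was -3.75 ± 0.349 on the log2 scale (edgeR adjusted p = 0.00337, DESeq2 4.42e-17, but edgeR 0.0538 with a replicate block), with averages of 1.97 CPM in N2 and 4.83 CPM in mbl-1 labelled L4, and of 2.28 and 0.406 CPM at the 2-day adult stage. Without N2 2-day adult replicate 3, edgeR called 64 genes, without mbl-1 2-day adult replicate 3 it called 5, and without both 879. Collagen genes had a median interaction of -1.01, and 1 of 102 rose and 27 fell when adjusted over the list alone (camera adjusted p = 0.185 with an estimated correlation). In N2, edgeR called 0 of 14027 genes between 2-day adult libraries and those labelled L4 (2098 at an unadjusted p under 0.05), and DESeq2 12 rises and 7 falls. edgeR called 1 without N2 2-day adult replicate 1. When adjusted over the list alone, 24 body wall muscle genes (median log2 0.61, camera adjusted p = 0.693 with an estimated correlation), 4 vitellogenin genes and 3 lipase genes were higher in N2 2-day adults. N2 2-day adult replicate 3, which stood apart, was the highest of its group, with 1010 CPM of unc-54 against 203 and 295 and 66520 CPM of vit-2 against 43130 and 40470.

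At L4, yolk protein genes fell in the 123CUG strains, and several genes read in the libraries of both 0CUG strains had no or nearly no reads in 123CUG. The L4 libraries of 0CUG strain 1 held transcripts that in 2-day adults were read in 0CUG strain 2 alone. A mixture of both strains in them stays open (below), so calls in all 4 pairs at L4 may rest on fewer than 2 independent control strains. All 6 vitellogenin genes fell, in all 4 pairs of strains and when adjusted over the list alone (median log2 -1.40, camera adjusted p = 0.154 with an estimated correlation). vit-2 fell by 1.40, from 1760 ± 391 to 659 ± 160 CPM (SE 0.0818, n = 6 and 6, edgeR adjusted p = 2.37e-10), and vit-3, whose reads are uncertain because vit-4 and vit-5 are near-identical, by 1.38, from 344 ± 91.1 to 127 ± 13.8 CPM. The ADAM metalloprotease gene sup-17 (DY3.7; I, 8792965 to 8797293) rose from 38.9 ± 3.62 to 175 ± 75.2 CPM (log2 2.08 ± 0.0605, edgeR adjusted p = 8.00e-15), with 243 ± 2.72 and 106 ± 5.57 CPM in 123CUG strains 1 and 2. With counts summed per strain (n = 2 and 2), vit-2 (edgeR adjusted p = 0.0623) and sup-17 (0.320) were not called.

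Among genes with a gene name, at least 5 CPM in the higher group and libraries that do not overlap, the largest rises called in all 4 pairs were those of srw-85 (C25F9.1; V, 19429440 to 19431039), a serpentine receptor gene (log2 3.28 ± 0.278), and sup-17. They were followed by the atlastin gene atln-2 (Y41E3.3; IV, 14981609 to 14996316; 2.07 ± 0.264, with dpy-4 antisense), the sodium channel gene unc-105 (C41C4.5; II, 8116356 to 8122861; 1.58 ± 0.104) and arrd-13 (R06B9.3; II, 13758414 to 13761227; 1.18 ± 0.0874, from 19.4 ± 2.36 to 43.1 ± 3.74 CPM), with edgeR adjusted p of at most 1.18e-05. With counts summed per strain srw-85 (0.0960), atln-2 (0.228) and unc-105 (0.649) were not called. unc-105 stood at 60.2 and 14.8 CPM in 123CUG strains 1 and 2 and at 10.6 and 9.73 CPM in the 0CUG strains. The largest falls under the same limits were near or at complete loss. The serpentine receptor gene srt-47 (Y41E3.12; IV, 15049411 to 15053371) had 0 reads in the 6 123CUG libraries and 5741 in the 6 0CUG libraries (26.98 ± 3.44 CPM), at least 1632-fold lower (edgeR adjusted p = 1.99e-14). dsl-4 (F16B12.2; X, 14090389 to 14095490), for a DSL-domain ligand, had 0 against 1226 reads, at least 349-fold lower. lips-12 (T13B5.6; II, 1112189 to 1114226), lipase-related, had 1 against 3421 reads, a ratio of 2918 (95% counting interval 523 to 115290). cky-1 (C15C8.2; V, 12736703 to 12740984), for a bHLH-PAS factor, had 3 against 1074 reads, a ratio of 305 (104.2 to 1480). spe-19 (Y113G7A.10; V, 20040927 to 20047398), needed for sperm activation and with Y113G7A.2 antisense, fell by 7.34, from 17.4 ± 2.69 to 0.101 ± 0.0485 CPM (SE 0.222, edgeR adjusted p = 8.40e-15). In 2-day adults srt-47, dsl-4 and spe-19 were read in 0CUG strain 2 and were at least 20-fold lower in 0CUG strain 1.

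Of 82 sperm genes, 0 rose, 54 fell and 28 were not called, and 63 fell when adjusted over the list alone. Sperm genes had a median log2 of -0.93 (camera adjusted p = 0.279 with an estimated correlation). Of these, spe-19 alone fell in all 4 pairs. spe-11 fell by 1.39, from 15.8 to 6.07 CPM (edgeR adjusted p = 3.27e-07), but was not called with counts summed per strain (0.269). Of 153 collagen genes, 10 rose, 29 fell and 114 were not called, and 18 rose and 31 fell when adjusted over the list alone. In all 4 pairs 17 fell. Their median was 0.01, their mean -0.30 and the test pointed down (camera adjusted p = 0.527 with an estimated correlation). col-139, which is near-identical to col-129 and uncertain for that reason, fell by 1.27, from 675 ± 179 to 271 ± 47.3 CPM (edgeR adjusted p = 2.51e-11), col-129 by 1.27 too, and col-68 (log2 1.52) and col-99 (log2 0.52) rose. With counts summed per strain none of these 4 was called (edgeR adjusted p = 0.109 for col-139 and 0.114 for col-129), and without 0CUG strain 1 col-99 had 0.23 (0.278). Of 172 intestinal immunity genes, 14 rose, 33 fell and 125 were not called, and 15 rose and 47 fell when adjusted over the list alone. Intestinal immunity genes had a median log2 of -0.15 (camera adjusted p = 0.398 with an estimated correlation). The saposin-like gene spp-2 fell by 1.49, from 31.2 ± 6.65 to 10.9 ± 1.70 CPM (edgeR adjusted p = 1.23e-07), clec-41 fell by 0.94, and clec-233 (log2 0.92) and irg-3 (log2 0.54) rose. With counts summed per strain clec-41 (0.0960), clec-233 (0.235) and irg-3 (0.590) were not called, and without 123CUG strain 1 irg-3 had 0.15 (edgeR adjusted p = 0.269). Of 7 pharyngeal muscle genes, 1 rose and 3 fell, 5 when adjusted over the list alone. Pharyngeal muscle genes had a median log2 of -1.25 (camera adjusted p = 0.383 with an estimated correlation).

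Several calls at L4 came from 123CUG strain 1. The nuclear receptor gene nhr-80 rose by a log2 of 1.02 ± 0.0631, with 137 and 35.8 CPM in 123CUG strains 1 and 2 against 37.9 and 32.9 CPM in the 0CUG strains. The desaturase genes fat-6 and fat-7, which NHR-80 is known to regulate and which as close paralogs have uncertain counts, fell by 0.98 and 1.26. fat-7 stood at 21.2 and 192 CPM against 151 and 160 CPM. Without 123CUG strain 1 its log2 difference was 0.31, that of nhr-80 0.02 and that of fat-6 -0.18 (edgeR adjusted p = 0.227). Of 23 fatty acid synthesis genes, 1 rose, 4 fell and 18 were not called, and 1 rose and 5 fell when adjusted over the list alone. Fatty acid synthesis genes had a median log2 of -0.03 (camera adjusted p = 0.479 with an estimated correlation). Of 47 body wall muscle genes, 6 rose, 0 fell and 41 were not called, with 6 when adjusted over the list alone. Body wall muscle genes had a median log2 of 0.18 (camera adjusted p = 0.398 with an estimated correlation). The integrin gene pat-3 rose by a log2 of 0.59 (177 and 109 against 93.6 and 94.8 CPM), and unc-98, which has pcyt-1 antisense, by 0.57 with 31.01 and 181 against 46.3 and 57.0 CPM, a difference of -0.70 without 123CUG strain 2. myo-3 had a log2 difference of 0.27 ± 0.150 (edgeR adjusted p = 0.292, but 0.00473 with no filter) and mbl-1 of 0.11 ± 0.102 (0.551). Of 27 splicing regulator genes, 6 rose, 0 fell and 21 were not called, and 7 rose when adjusted over the list alone. Splicing regulator genes had a median log2 of 0.12 (camera adjusted p = 0.383 with an estimated correlation). Among them rose sym-2 (log2 0.32, with pir-1 antisense) and mec-8 (log2 0.33, edgeR adjusted p = 0.0107, but 0.0511 without 123CUG strain 1 replicate 1). The calls of pat-3, sym-2 and mec-8 were also lost without 123CUG strain 1.

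Among the cpt genes at L4, cpt-4 rose by a log2 of 0.94 ± 0.0995 (edgeR adjusted p = 1.07e-06), with 59.0 ± 5.13 and 26.7 ± 1.77 CPM in 123CUG strains 1 and 2 and 26.1 ± 2.18 and 17.1 ± 4.35 CPM in 0CUG strains 1 and 2. Without 123CUG strain 1 its difference was 0.34 (edgeR adjusted p = 0.123). cpt-2 rose by 0.16 ± 0.0529 (edgeR adjusted p = 0.0494), a call lost when any of 11 of the 12 libraries was left out (up to 0.206, without 0CUG strain 2 replicate 2). cpt-1 had a difference of 0.20 ± 0.0888 (edgeR adjusted p = 0.156, but 0.28 and 0.0149 without 123CUG strain 1 replicate 3 and 0.09 and 0.531 without its replicate 1), and cpt-3, cpt-5 and cpt-6 had -0.48, 0.02 and -0.03 (edgeR adjusted p = 0.719, 0.950 and 0.876). cpt-3 ranged from -1.11 without 123CUG strain 1 replicate 1 to -0.20 without 123CUG strain 2 replicate 1. Of the list 2 genes rose and 0 fell, also when adjusted over the list alone (median 0.09, camera adjusted p = 0.396 with an estimated correlation).

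Over all genes at L4, 825 rose and 1517 fell of 16210 tested, DESeq2 called 997 and 1797, and 19 rose and 231 fell in all 4 pairs. The 825 rises became 475 without 0CUG strain 2 replicate 2 and 528 without 123CUG strain 1 replicate 1, and the 19 became 12 without 123CUG strain 2 replicate 3 and 35 without 0CUG strain 2 replicate 3. By pair, 123CUG strain 1 gave 1027 rises and 1691 falls against 0CUG strain 1 and 980 and 1221 against 0CUG strain 2. 123CUG strain 2 gave 473 and 950, and 235 and 377. The authors' deposited tables give 936 rises and 1765 falls, 863 and 1036, 681 and 1496, and 303 and 546 for the same pairs. Counts summed per strain, which take the strain as the unit (n = 2 and 2), gave 141 calls (9 rises and 132 falls), with 22 of 30 named genes losing theirs. Of the genes called in the main fit, 990 had an estimated change of at least 2-fold (162 and 828). Leaving out 123CUG strain 1 or 0CUG strain 1 gave 1300 or 1163 calls.

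Each strain also had genes that were far lower in the other strains in 2-day adults. At the 2-day adult stage such private genes, at 2 CPM or more in each library of 1 strain and with every library of the other strains at least 20-fold lower, numbered 14 in 123CUG strain 1, 9 in 123CUG strain 2, 19 in 0CUG strain 1 and 15 in 0CUG strain 2. In the L4 libraries of 0CUG strain 1, the 15 genes of 0CUG strain 2 had a median of 5.98 CPM, against 7.75 CPM in the L4 libraries of strain 2 and 0 CPM in 0CUG strain 1 at the 2-day adult stage. srt-47, dsl-4 and spe-19 are among these 15. Of the 231 falls in all 4 pairs at L4, 25 were of genes read, by the same limits, in 1 strain at either stage or in both 0CUG strains alone at L4.

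**Figure D4:**
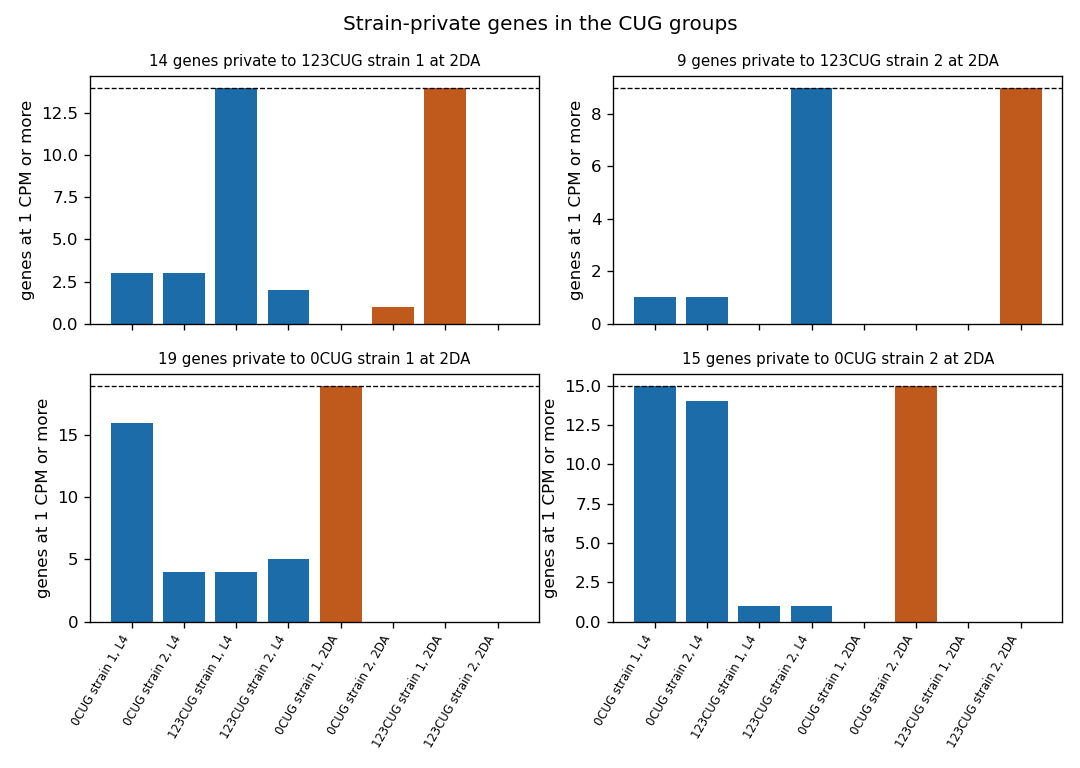
Number of genes private to each transgenic strain at the 2-day adult stage that reach 1 CPM in each of the 8 transgenic groups (bars), with the number of private genes of the strain as a dashed line. All 15 genes of 0CUG strain 2 reach 1 CPM in the L4 libraries of 0CUG strain 1.

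At the 2-day adult stage, 24 of 78 ribosomal protein genes rose and 7 of 13 eggshell genes fell in 123CUG against 0CUG (camera adjusted p = 0.708 for each with an estimated correlation). The short-chain dehydrogenase gene dhs-26 (ZK816.5; X, 3360685 to 3362493) rose 7.22-fold, from 3.50 ± 0.859 to 25.1 ± 5.22 CPM (log2 2.85 ± 0.170, n = 6 and 6, edgeR adjusted p = 4.40e-10). The acyl-CoA oxidase gene acox-1.2 (F08A8.2; I, 12942280 to 12946585) rose 3.21-fold, from 18.8 ± 6.76 to 58.0 ± 13.3 CPM (log2 1.68 ± 0.138, edgeR adjusted p = 3.75e-07). dsl-2 (W09G12.1; IV, 1202647 to 1204970) rose 2.90-fold, cutl-14 (B0511.5; I, 10628743 to 10631673; with sut-6 antisense) 2.83-fold and vet-1 (T05E7.5; I, 6200795 to 6202346) 2.55-fold. sysm-1 (T24B8.5; II, 9082682 to 9083142) fell by 1.73 on the log2 scale, from 91.1 ± 13.6 to 28.1 ± 7.81 CPM (SE 0.0941, edgeR adjusted p = 1.58e-10). The tetraspanin gene tsp-1 (C02F5.8; III, 8237995 to 8239423) fell by 1.97, the claudin-like gene clc-19 (T24C4.4; III, 872622 to 873531) by 1.90, the scramblase gene scrm-4 (F11A6.2; I, 11680504 to 11682364; with kpc-1 antisense) by 1.76 and drd-10 (C33G8.3; V, 7007612 to 7008339) by 1.55. Y49G5A.1 (V, 5286343 to 5287360), which has no gene name, fell by 3.55 (SE 0.274, edgeR adjusted p = 3.53e-08), which stood at 13.3 and 2.66 CPM in 0CUG strains 1 and 2. All of these were called in all 4 pairs, but vet-1 lost its call in the fit of both stages (log2 1.34, edgeR adjusted p = 0.118). With counts summed per strain all 38 named calls at this stage were lost (edgeR adjusted p of 0.402 or more). The other ways to group the 4 strains gave 74 and 151 genes called in all 4 pairs, against the real 58. Being called in all 4 pairs therefore does not tell construct from strain here.

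Of 78 ribosomal protein genes, 24 rose, 0 fell and 54 were not called, and 53 rose when adjusted over the list alone. Ribosomal protein genes had a median log2 of 0.25 (camera adjusted p = 0.708 with an estimated correlation). rpl-17 rose by a log2 of 0.78 (1933 and 3796 CPM in 123CUG strains 1 and 2 against 1691 and 1500 CPM) and rps-20 by 0.33, a call lost without 123CUG strain 1 (log2 still 0.31, edgeR adjusted p = 0.131) or 0CUG strain 2 (log2 0.14, 0.204). Of 150 intestinal immunity genes, 20 rose, 14 fell and 116 were not called, and 28 rose and 17 fell when adjusted over the list alone. Their median was 0.13 and their mean -0.04 (camera adjusted p = 0.846 with an estimated correlation). The saposin-like gene spp-5 rose from 733 ± 82.7 to 1516 ± 210 CPM (log2 1.06 ± 0.0975, edgeR adjusted p = 4.45e-07) and clec-10 by a log2 of 1.30, while clec-190 fell by 1.16 and spp-2 by 0.85. spp-2 stood at 28.1 and 25.8 CPM against 14.1 and 169 CPM and its difference was 0.90 without 0CUG strain 2. Of 96 collagen genes, 17 rose, 0 fell and 79 were not called, and 20 rose when adjusted over the list alone. Collagen genes had a median log2 of 0.31 (camera adjusted p = 0.742 with an estimated correlation). Among them col-42 (log2 0.82) and col-98 (log2 0.71) rose, but without 123CUG strain 1 they had 0.24 and 0.21 (edgeR adjusted p = 0.389 and 0.478), and col-98 also lost the call without 0CUG strain 2 (0.33, 0.0740). Of 25 mitochondrial fatty acid oxidation genes, 5 rose, 0 fell and 20 were not called, and 5 rose and 1 fell when adjusted over the list alone. Mitochondrial fatty acid oxidation genes had a median log2 of 0.15 (camera adjusted p = 0.768 with an estimated correlation). The thiolase gene kat-1 rose by a log2 of 0.60 ± 0.0705 (420 and 214 against 210 and 190 CPM, edgeR adjusted p = 9.57e-06) and acaa-2 by 0.34. Without 123CUG strain 1 kat-1 had 0.12 (edgeR adjusted p = 0.625) and acaa-2 0.15 (0.563), and without 0CUG strain 1 acaa-2 had 0.19 (0.227).

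Of 25 oocyte and early embryo genes, 1 rose, 6 fell and 18 were not called, and 1 rose and 9 fell when adjusted over the list alone. Oocyte and early embryo genes had a median log2 of -0.13 (camera adjusted p = 0.768 with an estimated correlation). puf-5 fell by 0.58, from 337 ± 41.4 to 223 ± 21.99 CPM (SE 0.0860, edgeR adjusted p = 0.000126) and puf-3, with afmd-2 antisense, by 0.41, a call lost without 123CUG strain 1 (log2 -0.43, 0.0622) or 0CUG strain 1 (log2 -0.24, 0.121). The rise of glh-1, by a log2 of 0.28, was lost when any of 7 of the 12 libraries was left out (edgeR adjusted p up to 0.112, without 0CUG strain 2 replicate 3). Of 13 eggshell genes, 0 rose, 7 fell and 6 were not called, and 2 rose and 10 fell when adjusted over the list alone. Eggshell genes had a median log2 of -0.36 (camera adjusted p = 0.708 with an estimated correlation). egg-1 (B0244.9 antisense) fell by 0.41 and egg-3 by 0.39. Without 0CUG strain 1 these were -0.20 and -0.19 (edgeR adjusted p = 0.195 for each), and without 123CUG strain 1 both calls were lost with differences of -0.40 and -0.34 (0.0696 and 0.136). Of 47 body wall muscle genes, 12 rose, 3 fell and 32 were not called, and 14 rose and 3 fell when adjusted over the list alone. Body wall muscle genes had a median log2 of 0.09 (camera adjusted p = 0.842 with an estimated correlation). The myosin light chain genes mlc-3 and mlc-2 (C36E6.2 antisense) rose by log2 0.67 and 0.62, and mlc-3 stood at 856 and 273 CPM in 123CUG strains 1 and 2 against 318 and 294 CPM. Without 123CUG strain 1 mlc-2 had 0.14 (edgeR adjusted p = 0.706). The titin-family gene ttn-1 fell by 1.02, lost without 0CUG strain 1 replicate 1 (edgeR adjusted p = 0.0882), and unc-22 by 0.50, lost without any of 7 of the 12 libraries (up to 0.145, also without 0CUG strain 1 replicate 1). ttn-1 was also not called without 123CUG strain 2 (0.101) or 0CUG strain 1 (log2 -0.61, 0.254), and unc-22 without 123CUG strain 2 (-0.16, 0.631) or 0CUG strain 2 (-0.24, 0.402).

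Of 21 fatty acid synthesis genes, 1 rose, 3 fell and 17 were not called, and 2 rose and 3 fell when adjusted over the list alone. Fatty acid synthesis genes had a median log2 of -0.09 (camera adjusted p = 0.842 with an estimated correlation). nhr-80 rose by a log2 of 0.95 ± 0.132, with 51.5 and 12.2 CPM in 123CUG strains 1 and 2 against 8.86 and 19.3 CPM, and fat-7 and fat-6 fell by 1.19 and 0.63. Without 123CUG strain 1 the differences of nhr-80 and mlc-3 were -0.09 and -0.15, and fat-6 had -0.32 (edgeR adjusted p = 0.246), with -0.27 (0.119) without 0CUG strain 2. Of 29 autophagy genes, 1 rose, 5 fell and 23 were not called, and 1 rose and 6 fell when adjusted over the list alone. Autophagy genes had a median log2 of -0.09 (camera adjusted p = 0.199 with an estimated correlation). atg-4.1 (Y87G2A.2 antisense) fell by 0.63 and atg-16.2 by 0.57, and epg-2 (tpxl-1 antisense) rose by a log2 of 0.81. Without 0CUG strain 1 atg-4.1 had -0.30 (edgeR adjusted p = 0.103) and epg-2 0.45 (0.0538), and without 123CUG strain 1 atg-16.2 had -0.43 (0.0562) and epg-2 0.62 (0.0728). Of the 6 cpt genes, cpt-5 rose by a log2 of 1.03 ± 0.127 (edgeR adjusted p = 1.60e-05), with 42.6 ± 0.352 and 30.1 ± 9.14 CPM in 123CUG strains 1 and 2 and 13.3 ± 2.41 and 23.4 ± 1.73 CPM in the 0CUG strains. It was called in 3 of the 4 pairs, with an edgeR adjusted p of 0.1044 for 123CUG strain 2 against 0CUG strain 2. cpt-1 fell by 0.20 (edgeR adjusted p = 0.0376), a call lost when any of 9 of the 12 libraries was left out (up to 0.102, without 123CUG strain 1 replicate 2), and its difference was -0.03 (0.921) without 123CUG strain 1. cpt-2, cpt-3, cpt-4 and cpt-6 had differences of 0.03, -0.78, 0.70 and 0.11 (edgeR adjusted p = 0.888, 0.288, 0.509 and 0.720), mbl-1 of 0.23 ± 0.124 (0.302) and myo-3 of -0.05 ± 0.140 (0.906). With 1 library left out cpt-3 ranged from -1.04 (without 123CUG strain 1 replicate 2) to -0.37 (without 0CUG strain 2 replicate 3) and cpt-6 from 0.05 to 0.17 (without 0CUG strain 1 replicate 1 or 2). Without 0CUG strain 2, mbl-1 (log2 0.83, edgeR adjusted p = 0.00244) and cpt-3 (-1.32, 0.0283) were called. Over the list, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.842 with an estimated correlation).

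Over all genes at the 2-day adult stage, 807 rose and 609 fell of 14070 tested, DESeq2 called 940 and 852, and 27 rose and 31 fell in all 4 pairs. The 27 rises became 15 without 123CUG strain 2 replicate 2 and 16 without 0CUG strain 2 replicate 1 or 2, and the 31 falls became 19 or 20 without 123CUG strain 1 replicate 1 or 2 and 19 without 0CUG strain 2 replicate 3. The authors' deposited tables give 2616 rises and 2348 falls for 123CUG strain 1 against 0CUG strain 1, 1284 and 1563 against 0CUG strain 2, and for 123CUG strain 2 1153 and 775, and 843 and 1415. With counts summed per strain, edgeR called 0 genes (345 at an unadjusted p under 0.05) and DESeq2 33. Between the 0CUG strains alone edgeR called 6276 genes, and both other ways to group the 4 strains in pairs gave more calls than 123CUG against 0CUG (up to 5333). Without 0CUG strain 1 the balance turned, with 1027 rises and 1527 falls, as it did for changes of at least 2-fold (166 and 194), and the pairs without that strain shared 497 rises and 753 falls. Of 38 named genes called at this stage, 14 lost the call and 2 reversed without 123CUG strain 1, and 9 lost it without 0CUG strain 1. Without 0CUG strain 1 replicate 1, edgeR called 937 genes (500 rises), and without 123CUG strain 2 replicate 3 it called 2172 (1374 rises).

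The 123CUG effect differed between stages for 1022 of 17248 genes in edgeR, 686 with a higher and 336 with a lower effect in 2-day adults. Without both groups of 0CUG strain 1 the balance turned, with 519 higher and 822 lower, and without 123CUG strain 2 2-day adult replicate 2 it was 451 and 471. The higher effects numbered 435 without 0CUG strain 1 2-day adult replicate 1 and 450 without 123CUG strain 1 2-day adult replicate 2. Between the 0CUG strains 191 genes were called at L4, where a mixture of both stays open (below), and 6276 in 2-day adults. A difference between stages can therefore also come from the makeup of the control libraries, which was not tested. The 6 vitellogenin genes all had a higher effect in 2-day adults, also when adjusted over the list alone. Their median interaction was 1.65 on the log2 scale, and camera called this list with an estimated correlation (adjusted p = 0.00362). For vit-1, vit-2 and vit-3 the mean log2 differences in 2-day adults were 0.53, 0.05 and 0.32. The 0CUG strains differed at that stage, with 21990 and 54310 CPM of vit-2 in strains 1 and 2, against 38020 and 33260 CPM in the 123CUG strains. The interaction of vit-1 was 1.93 ± 0.125 (edgeR adjusted p = 8.85e-11) and that of vit-3 1.72 ± 0.116. Under the rule for naming genes the largest interactions upward were those of lips-12 (8.94 ± 1.01), thn-1 (4.92 ± 0.828) and the lipase gene lipl-3 (4.45 ± 0.805), with edgeR adjusted p of at most 0.000886. Downward they were those of wrt-4 (-7.20 ± 1.24), the neural adhesion gene lad-2 (-4.40 ± 0.461, with Y54G2A.57 antisense) and atln-2 (-3.16 ± 0.721, edgeR adjusted p = 0.00723). wrt-4 had 1 read in the 123CUG 2-day adult libraries against 2343 in the 0CUG ones, a ratio of 2115 (95% counting interval 379 to 83578). The interaction of atln-2 rests on few 2-day adult reads, 20 in 123CUG and 40 in 0CUG. wrt-4 and lad-2 are among the genes private to 0CUG strain 1 in 2-day adults. The call of wrt-4 was lost without 0CUG strain 2 2-day adult replicate 1 (edgeR adjusted p = 0.9999). Of 157 collagen genes, 26 had a higher effect, 2 a lower one and 129 were not called, and 32 and 2 were called when adjusted over the list alone. Collagen genes had a median log2 of 0.56 (camera adjusted p = 0.243 with an estimated correlation). col-124 (1.78 ± 0.128, with qns-1 antisense) and col-140 (1.60 ± 0.122) were among them. The negative interactions of col-99 and col-68 were lost when any of 7 and of 19 of the 24 libraries was left out. Of 193 intestinal immunity genes, 27 had a higher and 3 a lower effect, and 32 and 5 when adjusted over the list alone. Intestinal immunity genes had a median log2 of 0.21 (camera adjusted p = 0.982 with an estimated correlation). They include clec-222 (3.95 ± 0.423), clec-10 (1.56 ± 0.185), lys-3 (-2.70 ± 0.510) and dod-24 (-0.88 ± 0.208). Of 13 genes regulated by DAF-16, the FOXO factor, 3 had a higher effect, and 7 when adjusted over the list alone (median 0.48, camera adjusted p = 0.0909 with an estimated correlation). dod-3 (2.17 ± 0.271) and the ferritin gene ftn-1 (1.93 ± 0.465) were among them. Without both groups of 0CUG strain 1, thn-1 (edgeR adjusted p = 0.123), wrt-4 (0.217), lad-2 (0.392), col-99, col-68, dod-24, dod-3 and ftn-1 were not called.

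Of 12613 genes tested in both genotype comparisons labelled L4, 304 rose in both (219 from independent lists, Fisher's exact test two-sided p = 4.40e-12) and 111 fell in both, fewer than the 199 of independent lists (p = 1.03e-14). More genes went opposite ways. In Fisher's exact test 466 rose in mbl-1 and fell in 123CUG against 284 from independent lists (p = 1.76e-38), and 125 fell in mbl-1 and rose in 123CUG against 154 (adjusted p = 0.0180). Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was -0.0637 and Spearman's rho -0.0262. Of the genes called in all 4 pairs of strains, 39 went the same way in mbl-1 and 59 the opposite way, and no direction passed Fisher's test (adjusted p from 0.307). unc-105 rose in both (log2 0.96 ± 0.258 in mbl-1, edgeR adjusted p = 0.00648), as did grd-10 (2.48 and 0.84), while rad-51 fell by 0.42 and 1.60 and hrpu-1 by 0.38 and 0.67. These 3 genes lie outside the rule for naming genes and were chosen after their values were seen. At the 2-day adult stage edgeR called 0 genes for mbl-1 and so none in both, and r was -0.164 over 13057 genes. In DESeq2 11 went the same way, and neither direction passed Fisher's exact test (adjusted p = 0.296 for 6 rises and 0.995 for 5 falls). The opposite way went 36, of which 28 fell in mbl-1 and rose in 123CUG against 4.86 from independent lists (adjusted p = 3.20e-14) and 8 the reverse against 2.87 (0.0180). The comparisons share no libraries, and the groups labelled L4 differ in stage between them.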

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

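The tests of a difference between stages and of other splits of the libraries were written before the results were seen, and the fit without 0CUG strain 1 was chosen after. The N2 and mbl-1 libraries labelled L4 had adult transcripts, so their difference from 2-day adults tests no change from larvae to adults. The difference of the mbl-1 effect between stages was called for 1 of 14027 genes, K12B6.11, with an interaction of -3.75 on the log2 scale. Of 100 splits of the libraries, the real one included, 8 gave at least as many calls, with up to 8861, so chance was not excluded for this count, and a split with so many calls points to a structure of the libraries other than genotype. The difference of the 123CUG effect between stages was called for 1022 of 17248 genes, 686 with a higher effect in 2-day adults and 336 with a lower one, but 519 and 822 without 0CUG strain 1. Of 100 splits only the real one gave as many (1 of 100, highest other 106), so a chance mix of libraries was excluded for this count. Such splits mix libraries of different strains, whose differences add to the spread. Strains, of which there are 2 per construct, were not exchanged as wholes, so the splits do not tell construct from strain. A mixture of the 0CUG strains at L4, which stays open (below), would bear on the 123CUG count as well.

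Among genes named in the report, 43 had a called difference of the 123CUG effect between stages. The log2 interactions, 2-day adult minus L4, were positive for lips-12 (8.94), thn-1 (4.92), lipl-3 (4.45), dhs-26 (3.99), clec-222 (3.95), dod-3 (2.17), acox-1.2 (1.96), ftn-1 (1.93), vit-1 (1.93), col-124 (1.78), vit-3 (1.72), col-140 (1.60), col-139 (1.57), clec-10 (1.56), vit-2 (1.48), col-129 (1.40), cpt-5 (1.04), spp-2 (0.66), col-42 (0.63), spp-5 (0.57), col-98 (0.49) and kat-1 (0.34). They were negative for cpt-1 (-0.38), atg-4.1 (-0.49), pat-3 (-0.50), arrd-13 (-0.59), egg-3 (-0.73), dod-24 (-0.88), col-99 (-0.95), egg-1 (-0.96), puf-5 (-1.13), ttn-1 (-1.24), col-68 (-1.29), scrm-4 (-1.31), sup-17 (-1.44), clc-19 (-1.46), sysm-1 (-1.75), tsp-1 (-1.82), lys-3 (-2.70), Y49G5A.1 (-2.91), atln-2 (-3.16), lad-2 (-4.40) and wrt-4 (-7.20). Yolk and cuticle collagen genes that fell in 123CUG at L4 (vit-2, vit-3, col-139, col-129) had no fall in 2-day adults. Their log2 differences there were 0.05, 0.32, 0.29 and 0.11. The effects on dhs-26, acox-1.2 and cpt-5, which rose in 2-day adults, were higher there than at L4. The interaction of a gene is a mean over strain differences, so for thn-1, lipl-3 and dod-3, which vary between strains, it need not match the pooled CPM. Without both groups of 0CUG strain 1, thn-1, wrt-4, lad-2, col-99, col-68, dod-24 and ftn-1 were not called and dod-3 stood at -0.16 and was not called, among the part of these genes looked up in that fit.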

How the results depend on the processing

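Leaving out the third 2-day adult libraries, the libraries low in rRNA, private genes or 0CUG strain 1 from the pairs or the interaction, and the oocyte covariate, were chosen after the data were seen; the other settings were fixed before. Totals not named stayed within 1.5 times the values in the report, among them those with RLE factors and protein-coding genes only, while some counts of rises or falls alone moved further. Pseudocount settings were not run, since the values are counts. Where a count fell with fewer libraries, strains or genes or a stricter rule, the setting itself removes power, but whether that was the cause was not tested. Leaving out 123CUG strain 1 or strain 2 gave 1300 or 2580 calls at L4 and 511 or 2320 in 2-day adults. Where a count rose or its direction turned, the cause was not tested either.

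For mbl-1 at L4 (6821 calls) a cutoff of an estimated 2-fold change, put on the calls without a new test, kept 1697 genes. A fit with 4 groups called 996, and leaving out 1 library gave 5095 to 7871. For 123CUG at L4 (2342 calls) the 2-fold cutoff kept 990 and counts summed per strain gave 141. Both stages in 1 fit gave 1522, leaving out 123CUG strain 1 1300 and 0CUG strain 1 1163, and leaving out 1 library 1734 to 2838. Genes called in all 4 pairs (250) numbered 394 with no filter and 203 to 294 without 1 library. For mbl-1 at the 2-day adult stage (0 calls in edgeR, 695 at an unadjusted p under 0.05) DESeq2 called 132 genes, a fit with 4 groups 79, the oocyte covariate 174, a fit without the third libraries 4416, and leaving out 1 library 0 to 0. For 123CUG at the 2-day adult stage (1416 calls) the 2-fold cutoff kept 360. Counts summed per strain gave 0 (345 at an unadjusted p under 0.05, DESeq2 33). Leaving out 123CUG strain 1 gave 511, 123CUG strain 2 2320, 0CUG strain 1 2554 (1027 rises and 1527 falls, against 807 and 609) and 0CUG strain 2 3535. Leaving out 1 library gave 937 (without 0CUG strain 1 replicate 1) to 2172 (without 123CUG strain 2 replicate 3), and without both libraries low in rRNA 947. Genes called in all 4 pairs (58) numbered 89 with no filter, 33 with each pair fitted alone, 1250 in the pairs without 0CUG strain 1 (497 rises and 753 falls), 31 without both libraries low in rRNA and 39 to 82 without 1 library.

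The difference of the mbl-1 effect between stages (1 call) gave 173 calls in DESeq2, 879 without the third libraries and 1 to 64 without 1 library (64 without N2 2-day adult replicate 3). That of the 123CUG effect (1022 calls) gave 1538 in DESeq2 and 738 to 1090 without 1 library. Its share of higher effects was 67.1%, 56.0% in DESeq2, 53.5% with no filter, 48.9% without 123CUG strain 2 2-day adult replicate 2 and 38.7% without both groups of 0CUG strain 1. The N2 stage comparison (0 calls, 2098 at an unadjusted p under 0.05) gave 19 in DESeq2 and 0 to 1 without 1 library (1 without N2 2-day adult replicate 1). The same direction in mbl-1 and 123CUG at L4 was called for 415 genes and for 39 with all 4 pairs required, and at the 2-day adult stage for 0 and in DESeq2 for 11. Over all comparisons 1 list was called with an estimated correlation, 90 with a preset one and 41 with fry.

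Single genes reversed when a strain was left out. At L4 these were fat-7 (0.31 without 123CUG strain 1) and unc-98 (-0.70 without 123CUG strain 2). In 2-day adults they were nhr-80 (-0.0877) and mlc-3 (-0.15) without 123CUG strain 1, and glh-1 (-0.0644) and spp-2 (0.90) without 0CUG strain 2, and in the interaction dod-3 (-0.16 without 0CUG strain 1). Of 3242 values over 149 combinations of a named gene and a comparison, 3005 kept the side of the threshold, 220 lost the call, 10 gained one and 7 reversed. A change of sign in a gene called in neither setting is among the 3005, as for cpt-6 in 123CUG at L4. With counts summed per strain, 22 of 30 named 123CUG calls at L4 were lost (adjusted p 0.0623 or more) and 38 of 38 at the 2-day adult stage (0.402 or more). With no filter myo-3 gained a call at L4 (0.00473). No other scaling moved the median log2 by over 0.0471.

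The replicate numbers do not pair the libraries: 1 of 48 pairs of equal number had a correlation of deviations above 0.1 (range -0.488 to 0.121 over 17482 genes), and in 0 of 16 pairs of groups did every one. A replicate block gave 7067 calls for mbl-1 and 1998 for 123CUG at L4 (223 in all 4 pairs), 0 (242 at an unadjusted p under 0.05, DESeq2 49) and 1510 (70) at the 2-day adult stage, 0 (990, DESeq2 68) and 947 for the interactions, and 0 (1169, DESeq2 5) for the N2 stage. Depth limits low genes, and intervals and floors cover counting error only. The simulation changed only genes with a mean of at least 5 CPM. In it 25.4% of genes changed 1.5-fold at L4 and 26.9% at the 2-day adult stage were called in all 4 pairs.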

Other observations

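The tests of older animals, of exchanged labels and of oocyte share, and that of a switch by stage, were chosen after the result was seen; those of a shift between library sets, library size, a mixture of strains and other splits were written before.

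In mbl-1 libraries labelled L4, where 51.4% of all genes were called, further lists held called genes but camera called none of them (adjusted p = 0.619 to 0.976 with an estimated correlation). Of 35 intestinal genes, 27 rose and 1 fell, of 10 neuromuscular receptor genes 6 rose and 0 fell (7 when adjusted over the list alone), and of 78 ribosomal protein genes 37 rose and 0 fell (30 when adjusted over the list alone). RNA interference genes fell in 17 of 28 cases and rose in 3 (20 and 3 when adjusted over the list alone), nonsense-mediated decay genes fell in 5 of 9, and of 26 splicing regulator genes 5 rose and 8 fell. Detoxification genes rose in 55 of 124 cases and fell in 15, lipase genes rose in 6 of 9 and fell in 1, antimicrobial peptide genes of the epidermis rose in 7 of 13 and fell in 1, and vitamin B12 and propionate genes rose in 6 of 14. Rises and falls were 9 and 9 of 40 for moulting, 7 and 6 of 19 for energy sensing, 8 and 4 of 33 for histone, 5 and 4 of 16 for heat shock, 5 and 4 of 13 for DAF-16 regulated, 4 and 6 of 29 for autophagy and 3 and 3 of 10 for mitochondrial stress response genes. Of 12 mitochondrial DNA genes 4 rose, of 3 pharyngeal muscle genes 1 rose and of 6 vitellogenin genes 1 fell.

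In the 123CUG strains at L4, 6 of 15 epidermal antimicrobial peptide genes rose and 1 fell (8 and 2 when adjusted over the list alone), 9 of 52 neuronal genes rose and 1 fell, 6 of 45 histone genes rose and 7 of 38 intestinal genes fell (camera adjusted p = 0.396 to 0.434 with an estimated correlation). In 2-day adults 6 of 37 oxidative phosphorylation genes rose and 0 fell, and 18 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.708 with an estimated correlation). On the stage scale the L4 libraries averaged -0.0266 and -0.000927 in 123CUG strains 1 and 2 and 0.0356 and -0.00477 in the 0CUG strains. Across 16210 genes, which are not independent replicates, the 123CUG effect at L4 had r = 0.0735 and rho = -0.0410 with the stage change. Its median log2 was -0.119 over 1638 genes higher in adults and 0.1245 over 1916 genes lower in adults.

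The N2 and mbl-1 libraries labelled L4 had adult transcripts. An exchange of the stage labels was argued against by the lowest 2-day adult library, at 0.849 on the stage scale where an exchange needs a value near the transgenic L4 libraries, and a shift between library sets by the adult-high genes. These stood above 0CUG by a median log2 of 3.19 at L4 and of -0.011 in 2-day adults, a ratio of -0.00345 where a shift needs about 1. Animals older than L4 in these libraries remain a candidate explanation, as the lowest of the 6 stood at 0.908. The mbl-1 comparison labelled L4 may therefore be one of adults, and no biological explanation was tested.

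The third 2-day adult libraries of N2 and mbl-1 stood apart from their groups. A different share of oocyte and embryo transcripts had the values it needs, with a median log2 difference of the oocyte list of -0.900 in N2 replicate 3 and 1.16 in mbl-1 replicate 3, although mbl-1 replicate 1 also stood at -0.971. Library size was argued against for mbl-1 replicate 3, at 39.5 M reads inside the range of the others, and is open for N2 replicate 3 at 34.3 M reads, the lowest. An exchange of the labels of both libraries remains open: of 98 genes that separate the genotypes at least 8-fold, 57.1% lay nearer the own genotype in N2 replicate 3 and 46.9% in mbl-1 replicate 3, and on genes moving against the oocyte axis 55.2% to 88.9% and 62.2% to 81.0% did. mbl-1 replicate 1, whose label is not doubted, had 22.2% to 58.0% on the same genes. The axis was taken from the 2-day adult libraries other than the third, mbl-1 replicate 1 among them. The choice of genes thus bears on its share, which is no benchmark for the third libraries. Of the 10 splits of the 6 libraries, the one that exchanges these libraries gave 6146 calls and the real one 0, which points to a structure of the samples.

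The L4 libraries of 0CUG strain 1 held transcripts of genes that in 2-day adults were read in 0CUG strain 2 alone. An exchange of strain labels was argued against, as 89.5% of the 19 genes private to 0CUG strain 1 stood in its L4 libraries above every other L4 library. A switch by stage unrelated to strain 2 stays open: 100% of the 15 genes of strain 2 were at 1 CPM or more, but these genes define the pattern and so decide nothing. A mixture of both 0CUG strains in these libraries has the values it needs, since 191 genes differed between the 0CUG strains at L4, against 1561 between the 123CUG strains at L4 and 6276 between the 0CUG strains in 2-day adults. If it were a mixture, the L4 controls could be closer to 1 strain than to 2. Any call in all 4 pairs at L4, the falls of srt-47, dsl-4 and spe-19 among them, may then rest on 1 control strain. A biological difference between the strains was not tested.

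Other splits of the libraries were counted for each number of calls, the real split included. For 123CUG at L4, 1 of 100 splits reached the real 2342 (highest other 573), and for genes called in all 4 pairs 1 of 100 reached 250 (highest other 1), so a chance split of libraries was excluded. In 2-day adults 2 of 100 reached 1416 (highest other 1783) and 1 of 100 reached 58 in all 4 pairs (highest other 2), which excludes it too. Such splits mix libraries of different strains, whose differences add to the spread, so they exclude a chance mix of libraries and do not tell construct from strain. The 4 strains make only 3 groupings, too few for a share under 0.05. At L4 1 of 3 reached 2342 (highest other 992) and 1 of 3 reached 250 (highest other 19), and at the 2-day adult stage 3 of 3 reached 1416 (highest other 5333) and 3 of 3 reached 58 (highest other 151). The 10 splits of 3 against 3 libraries are too few as well: 1 of 10 reached the 6821 calls of mbl-1 at L4 (highest other 0), 10 of 10 the 0 of mbl-1 at the 2-day adult stage and 10 of 10 the 0 of the N2 stage comparison (highest other 0). For gene lists with an estimated correlation, 10 of 10 splits reached the 0 called for mbl-1 at each stage (highest other 0), and 100 of 100 the 0 called for 123CUG at each stage (highest other 3 at L4 and 1 in 2-day adults). As every split reaches 0, these counts of 0 decide nothing on chance.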
